A study of Mus musculus with 4 samples.

How the data were processed

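Total RNA of primary VSMCs from mouse thoracic aorta was hybridised to Mouse Gene ST 2.1 array strips, per the series' design text, after whole-transcriptome amplification from 10 ng with the Ovation PicoSL WTA kit, per the labels' protocols. The adventitia had been removed, the aortic pieces digested with collagenase and the cells cultured for 5 days in medium with serum. Per the labels, VSMC identity was checked by staining for alpha actin, calponin and smoothelin. The 4 arrays fall into 2 Cre-negative controls and 2 Cre-positive knockouts by their titles. Per the design text the cells came from 2 separate pairs of mice, so the p-values measure the spread between arrays that differ in mouse, culture and hybridisation together. The titles number the arrays 1 and 2 in each group, without saying that a number marks a pair.

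The deposited table holds log2 expression values for 41345 rows, background-corrected, normalised and summarised per transcript cluster with RMA, per the submitters' processing notes. The log base was taken from the range of the values, 1.17 to 12.4. The software version, the chip definition and the genome build are not given in the sources used here, so no coordinates are reported. No ratio between the levels of different probes was taken, and levels served only to set dim genes apart, to match random lists and to pick the members of a list with the highest control mean. Sequencing depth does not apply to arrays, and the number of arrays limits the precision.

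Rows were named through the platform's probe annotation: 23521 rows had 1 gene symbol, 1814 had several and 16010 were not listed there and are unnamed here. The NCBI gene numbers of 23328 rows with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No gene was named from a row with several symbols. The 22180 genes included 1082 with more than 1 row, for which the row with the highest mean over the 4 arrays was kept. Genes with a mean below the median of all row means (3.02) were left out, 9630 in number, and 12550 were tested. The 7367 rows above that level with no or several symbols were fitted separately: limma called 0 of them (smallest adjusted p 0.518), with 679 at an unadjusted p under 0.05.

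Each gene was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), knockout minus control, without covariates, and called at a Benjamini-Hochberg adjusted p under 0.05. Intervals are 95% intervals from that fit. Gene lists were tested two-sided with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 of 42 lists that had at least 3 tested members. Camera with an estimated correlation and fry were alternatives. Fry's directional p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction. A figure library, matplotlib 3.10.9, drew the plots.

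The groups, tests, gene lists, naming rule and alternatives were chosen before the data were examined. The rule names Mmp14, Tagln and Apoe in every case. Per direction it takes up to 12 called genes with the largest difference and no overlap between groups, and fills free places with genes of smallest limma p and no overlap, given as values. Predicted or unnamed genes, small RNAs and olfactory or vomeronasal receptors are skipped. The result of 1 gene that the rule chose as lower is not reported here. Within each list it names up to 4 members with the largest absolute difference and no overlap. Kdr, Vwf and Flt1 were named outside the rule, after their values were seen, and are left out of the counts over named genes. C1qc, Cd55, Lyz2, Cyba, Lcp1, Arhgdib, Palmd, Tm4sf1, Cd93, Fli1, Stab1, Ecscr, Adgrl4, S1pr1, Ccn1, Ccn2, Acta2, Myh11, Pdgfra and Pdgfrb fall outside the rule and were chosen after their values were seen, as were the lists without members shared with the macrophage or endothelial list.

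Alternatives were the title number as a replicate block, no filter or a 75th percentile filter on dim genes, a second quantile normalisation, arrays centred on their median, the mean of all rows of a gene, eBayes with a trend or with a trend and robust estimation, array weights, other thresholds and leaving out each array in turn. A group left with a single array was assumed to vary like the other group. The filters also change which members of a list are tested. Bootstrap intervals resampled list members, not arrays, 10000 times, so they carry no spread between arrays. Random lists, 10000 per list, were matched on expression in 20 bins.

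The fit was tested on simulated data for the knockout and control comparison with 12550 genes. It called 3 of 50 genes changed by 1 log2 unit, 40 of 50 changed by 2, 48 of 50 changed by 3 and 49 of 50 changed by 4, with 8 false calls. Camera recovered the simulated list of 27 shifted members (adjusted p = 5.51e-36) and called 0 others. The simulated genes varied independently of one another, so the simulation does not show how often camera calls lists of correlated genes falsely. Their variances were drawn from the fitted prior, and many changes were planted at once. The shares recovered therefore need not hold for the measured arrays, where 0 genes were called, although Clic5 differed by -3.65.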

Results

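Gene expression was measured in primary vascular smooth muscle cells (VSMCs), the contractile cells of the arterial media, grown from the thoracic aortas of mice without Apoe. Loss of Apoe, a carrier protein of plasma lipoproteins, raises plasma cholesterol, and the mice had eaten a Western diet for 3 months. All animals carried floxed alleles of Mmp14, the gene of the membrane-anchored collagenase MT1-MMP. In the knockout group a Cre recombinase driven from the SM22α (Tagln) promoter, active in smooth muscle, was present, and in the control group it was not. Each group had 2 arrays, from cells cultured for 5 days. The comparison of knockout with control cells addressed which transcripts depend on MT1-MMP in VSMCs of Apoe-null mice. Each array gave log2 values for 41345 rows, of which 12550 genes with a symbol of their own and a mean level of at least 3.02 were tested. The array medians were 3.01 and 3.01 in the controls and 3.05 and 3.03 in the knockouts. Across rows, which are not independent replicates, Pearson's r was 0.981 between the control arrays, 0.982 between the knockout arrays and 0.974 to 0.980 across groups. The number of arrays limited the precision throughout, since 2 against 2 cannot give a two-sided exact permutation p below 0.333.

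Mmp14, the targeted gene, had log2 values of 8.71 and 9.05 in the control arrays and 8.27 and 8.19 in the knockout arrays. The group means were 8.88 ± 0.24 (SD, n = 2) and 8.23 ± 0.05 (SD, n = 2), a log2 difference of -0.65 (SE 0.17, 95% interval -1.10 to -0.20), or 0.636 times the control level. Both knockout arrays lay below both control arrays, but the difference did not pass the genome-wide test (limma, adjusted p = 0.319). The value summarises probes over the whole transcript cluster, some of which can lie outside the floxed exons, so it checks the labels only in part. Tagln, whose promoter drove Cre, averaged 10.1 ± 0.49 in the controls and 10.1 ± 0.42 in the knockouts (SD, n = 2 each), a difference of -0.01. Without control replicate 1 the Tagln difference was 0.34, and without control replicate 2 it was -0.36. Apoe, disrupted in both groups, read 4.99 ± 0.02 and 4.63 ± 0.25 (SD, n = 2 each), a difference of -0.36 (limma, adjusted p = 0.502).

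Knockout cultures had higher levels of macrophage transcripts and lower levels of YAP/TAZ target transcripts and of the endothelial transcripts on the list fixed in advance than control cultures. A second endothelial list, added later, had members on both sides of 0. The macrophage list had a median log2 difference of 1.16, a 2.23-fold ratio, the endothelial list of -0.53 and the YAP/TAZ target list of -0.48. The contractile genes of smooth muscle had a median difference of -0.01, with 10 of 22 members higher and 12 lower. Of 40 gene lists tested with camera, 9 passed at an adjusted p under 0.05, 5 higher and 4 lower in the knockouts. With an inter-gene correlation estimated from the 4 arrays, 0 of the 40 lists passed, and the smallest adjusted p was 0.713 with an estimated correlation.

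**Figure D1:**
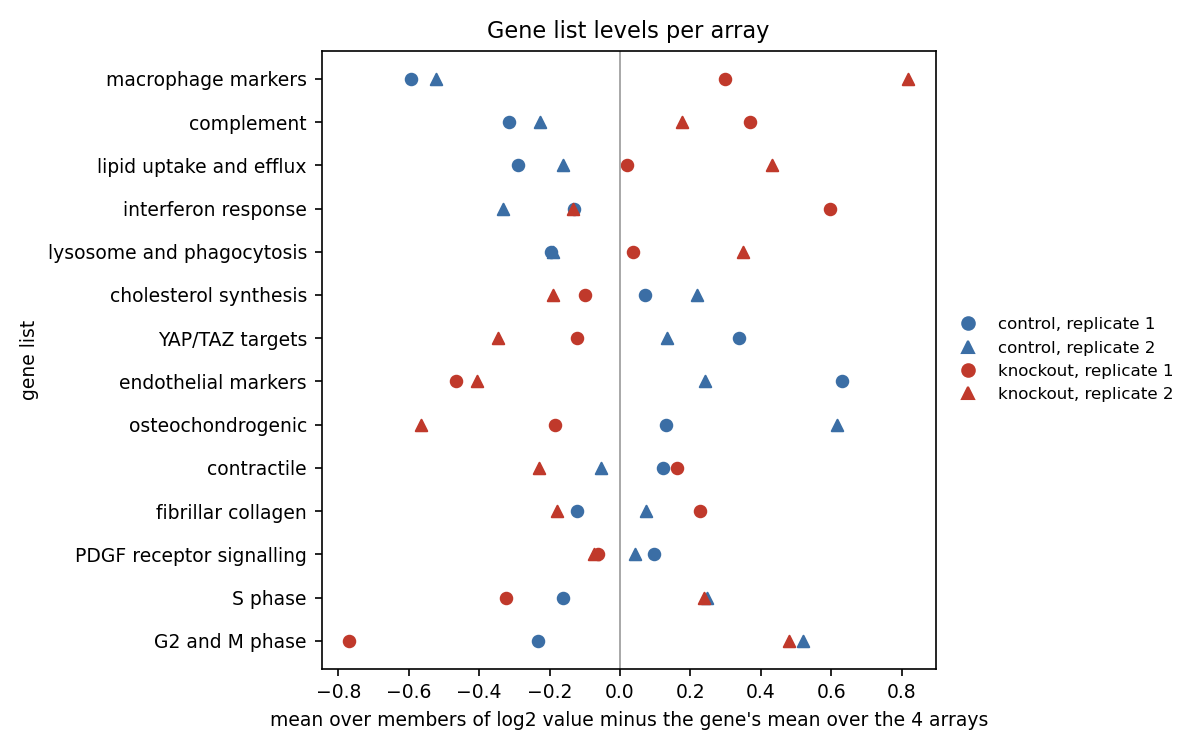
Mean over the members of 14 gene lists of the log2 value minus the gene's mean over the 4 arrays (x axis, log2 units), for each list (y axis) and array, with control arrays in blue, knockout arrays in red, replicate 1 as circles and replicate 2 as triangles. For the macrophage list the control arrays sat at -0.59 and -0.52 and the knockout arrays at 0.30 and 0.82, while for the G2 and M phase list both arrays numbered 2 lay above both arrays numbered 1.

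No single gene passed the genome-wide test: limma called 0 of 12550 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.104. There were 1465 genes at an unadjusted p under 0.05, 614 higher and 851 lower in the knockouts, against 627.5 genes given by chance. Without control replicate 1 that count was 975. The knockout arrays lay wholly above or below the control arrays for 5556 genes (44.3%), where chance gives 33.3%. Among these, 225 genes were higher and 162 lower by at least 1 log2 unit. The genes named next had the smallest limma p in each direction among those without overlap, and none of them passed the adjustment over all genes.

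The 12 genes named as higher in the knockout arrays had differences of 1.38 to 2.35, with adjusted p-values (limma) of 0.121 to 0.144. Several are known from leukocytes. Ptprc, the leukocyte common antigen CD45, averaged 6.64 ± 0.05 in the controls and 8.39 ± 0.19 in the knockouts (SD, n = 2 each), a difference of 1.75 (SE 0.16). Adgre1, which encodes the macrophage surface protein F4/80, differed by 1.74 (SE 0.17), and Cd14, a co-receptor for bacterial lipopolysaccharide, by 1.38 (SE 0.14). The largest of these 12 differences was that of Cd200r1, an inhibitory receptor of myeloid cells, at 2.35 (SE 0.22), or 5.11-fold. Cyth4 differed by 1.97, Rasgef1b by 1.95, Slfn2 by 1.89, Myo1f, a class I myosin, by 1.83 and Ms4a6d by 1.83. Blnk, a B cell linker protein, differed by 1.68, the metalloprotease gene Adam8 by 1.65 and Hpgds, the hematopoietic prostaglandin D synthase, by 1.40.

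The 12 genes chosen by the same rule as lower had differences of -3.65 to -1.21, with adjusted p-values (limma) of 0.104 to 0.147. Several are known from vascular endothelium. Ptprb, the vascular endothelial protein tyrosine phosphatase, averaged 6.44 ± 0.11 in the controls and 3.56 ± 0.16 in the knockouts (SD, n = 2 each), a difference of -2.88 (SE 0.16). Pecam1, the endothelial adhesion molecule CD31, differed by -2.49 (SE 0.18), Selp, which encodes P-selectin, by -2.46 (SE 0.16), and Myct1 by -3.02 (SE 0.28). Clic5, a chloride intracellular channel family member, differed by -3.65 (SE 0.23), with control arrays at 6.40 and 6.93 and knockout arrays at 2.90 and 3.12. The carbonic anhydrase family gene Car8 differed by -3.02, Crct1 by -3.06, Itgbl1 by -2.75 and Ano1, a calcium-activated chloride channel, by -2.14. The knockout means of Clic5 and Ano1 lay below the filter level of 3.02, so the sizes of both differences may be lower bounds. No background level was measured. Prex2 differed by -1.30 and Clba1 by -1.21.

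**Figure D2:**
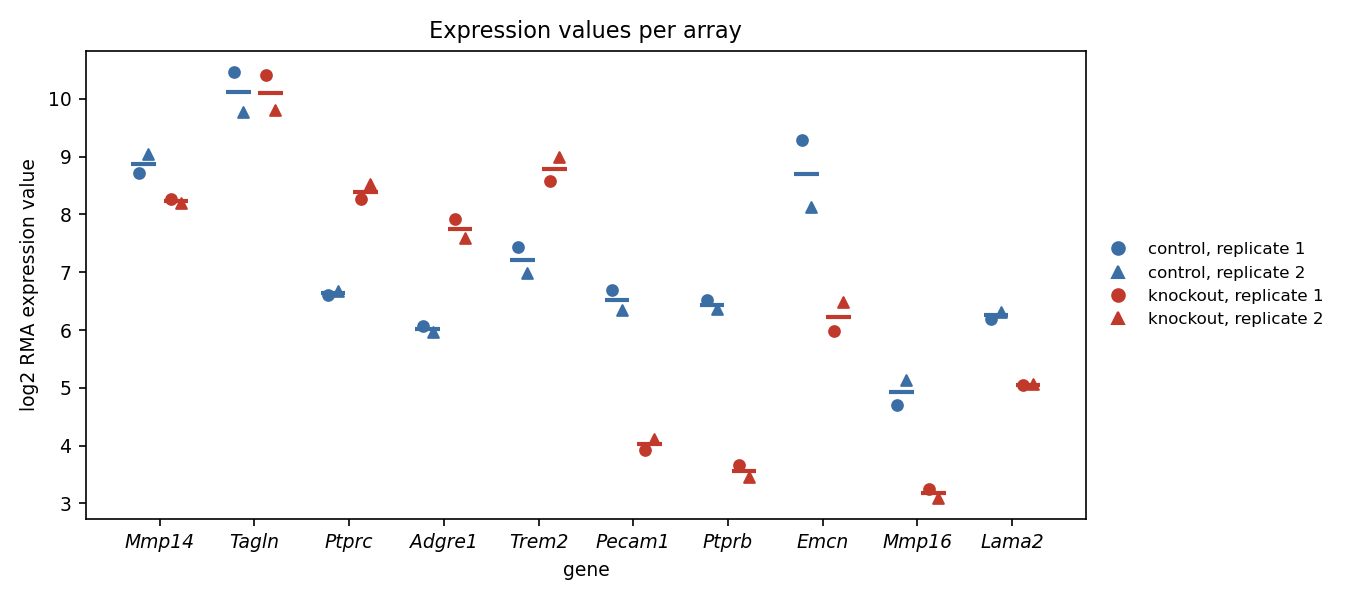
Log2 RMA expression value (y axis) of 10 named genes (x axis) in each array, with control arrays in blue, knockout arrays in red, replicate 1 as circles, replicate 2 as triangles and horizontal bars for group means. Mmp14 averaged 8.88 in the controls and 8.23 in the knockouts, Ptprc, Adgre1 and Trem2 sat higher in the knockouts, and Pecam1, Ptprb, Emcn, Mmp16 and Lama2 sat lower.

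All 27 tested members of the macrophage list were higher in the knockout arrays, and for 23 of them the groups did not overlap. The shift passed camera (adjusted p = 1.19e-23; adjusted p = 0.713 with an estimated correlation). Counted with p-values adjusted over the list alone, 19 members passed, all higher, against 0 adjusted over all genes. Mrc1, the mannose receptor, averaged 5.30 ± 0.58 and 7.38 ± 0.49 (SD, n = 2 each), a difference of 2.08 (SE 0.38), and Trem2, a lipid-sensing receptor of myeloid cells, differed by 1.57 (SE 0.24). Macrophage transcripts were already present in the control arrays, where Lyz2, the lysozyme gene of myeloid cells, averaged 11.0 and Cd68 averaged 9.79. Lyz2 differed by 0.22 and Cd68 by 0.82.

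Of 20 genes tested on the endothelial list, 17 were lower and 3 higher in the knockout arrays. The 3 higher were Kdr (0.32, without overlap between groups), Vwf (0.29) and Flt1 (0.10). Camera gave an adjusted p of 8.23e-06 for the list, and adjusted p = 0.713 with an estimated correlation. Adjusted over the list alone, 7 genes passed and all were lower, against 0 adjusted over all genes. Beside Ptprb and Pecam1, the largest differences were those of Cdh5, which encodes VE-cadherin, at -2.51 (SE 0.63), and of Emcn, an endothelial sialomucin, at -2.48 (SE 0.43). The list's median was -0.53 over all arrays and -0.32 without control replicate 1. It was -0.35 with no filter on dim genes and -2.49 with the stricter filter, and the call held in both. The filter changes which members are tested, so these medians cover different genes. A second list of 22 other endothelial genes had 12 members higher and 10 lower and a median of 0.069, above 94.0% of random lists matched on expression, and 14 of the 22 had a control mean under 4, with little room to fall.

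All 20 tested members of the list of targets of YAP and TAZ, transcriptional co-activators that respond to matrix stiffness and cell tension, were lower in the knockout arrays. The median difference of -0.48 passed camera (adjusted p = 1.60e-05; adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, 2 members passed, Nt5e and Ptpn14, against 0 adjusted over all genes. Nt5e, the ecto-5'-nucleotidase CD73, averaged 4.49 ± 0.29 and 3.32 ± 0.26 (SD, n = 2 each), a difference of -1.17 (SE 0.22). Ptpn14 differed by -0.77 (SE 0.15), Foxf2 by -0.78 and Lats2, a kinase of the Hippo pathway, by -0.70. The matrix-associated proteins Ccn1 and Ccn2, widely used readouts of YAP activity, differed by -0.22 (SE 0.25) and -0.07 (SE 0.18), and their groups overlapped. Both changed sign, to 0.08 and 0.11, without knockout replicate 2, where the list's median was -0.29. The macrophage list, with a median of 1.16, and the endothelial list, with -0.53, moved between the same groups.

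Lipid handling, lysosome and complement genes were higher together with the macrophage list. The lipid uptake and efflux list had 17 of 21 members higher and a median of 0.53 (camera adjusted p = 1.51e-05; adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, 2 of its members passed, against 0 over all genes: Msr1, the macrophage scavenger receptor, at 1.66 (SE 0.20), and Nceh1, a neutral cholesterol ester hydrolase, at 1.06 (SE 0.15). Lipa, the lysosomal acid lipase, differed by 0.84 and Pltp, the phospholipid transfer protein, by 1.11. The lysosome and phagocytosis list had 17 of 18 members higher and a median of 0.41 (camera adjusted p = 1.95e-07; adjusted p = 0.713 with an estimated correlation), with 0 members past the test adjusted over the list alone or over all genes. Hexa, a subunit of beta-hexosaminidase, differed by 0.71, the protease gene Ctss by 0.67 and Gusb, beta-glucuronidase, by 0.57. The complement list had 12 of 13 members higher and a median of 0.56 (camera adjusted p = 4.75e-05; adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, C1qa (1.55), C1qb (1.16), C1qc (1.00) and C3ar1 (1.35) passed as higher and Cd55, an inhibitor of complement activation, as lower (-0.98), against 0 over all genes, and the properdin gene Cfp differed by 1.03.

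Without knockout replicate 2 the medians of the lipid and lysosome lists were 0.12 and 0.23. The complement median was 0.37 without control replicate 1 and 0.13 without knockout replicate 1. It was 0.28 with no filter on dim genes and 1.01 with the stricter filter, each over a different set of members. The call was lost (median 0.28, adjusted p = 0.0569 by camera in limma) when the members shared with the macrophage list were left out. The lysosome list without its shared members had a median of 0.33 and an adjusted p of 8.23e-06 by camera, and the lipid list shared none. The lipid list still held Msr1, the macrophage scavenger receptor. Leaving out shared members therefore does not separate these lists from the macrophage shift.

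The interferon response list had 23 of 26 members higher in the knockout arrays and a median of 0.42 (camera adjusted p = 2.24e-05; adjusted p = 0.713 with an estimated correlation). Psmb8, an immunoproteasome subunit, differed by 0.99 (SE 0.14) and was the only member past the test adjusted over the list alone, against 0 over all genes. Psmb9, another subunit, differed by 1.55, Oasl2 by 0.87 and Ifit2 by -0.64. Without knockout replicate 1 the Oasl2 difference was 0.11, and without knockout replicate 2 it was 1.64. The list's call was lost without knockout replicate 1 (median 0.11, adjusted p = 0.328 by camera in limma, from 8.06e-16 over refits), and the median was 0.73 without knockout replicate 2 and 0.27 without control replicate 2. The list's mean deviation was 0.60 in knockout replicate 1 and -0.13 in knockout replicate 2. The macrophage list, with 27 of 27 members higher and a median of 1.16, moved between the same groups.

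Cholesterol synthesis genes were lower in the knockout arrays, in 15 of 17 members and with a median of -0.27 (camera adjusted p = 0.00508; adjusted p = 0.713 with an estimated correlation). None passed adjusted over the list alone or over all genes. Lss, lanosterol synthase, differed by -0.74 (SE 0.16), Cyp51 by -0.68 (SE 0.26), Sqle, squalene epoxidase, by -0.51 (SE 0.20) and Fdps by -0.42 (SE 0.20). The call was lost without control replicate 2 (median -0.19, adjusted p = 0.143 by camera in limma) and with a stricter filter on dim genes (adjusted p = 0.0658, from 0.00018 over refits). The macrophage list, with a median of 1.16, and the endothelial list, with -0.53, moved between the same groups.

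The osteochondrogenic list, genes of bone and cartilage that also appear in calcifying vessels, had 8 of 10 members lower and a median of -0.61 (camera adjusted p = 0.0214; adjusted p = 0.713 with an estimated correlation). Tnfrsf11b, which encodes osteoprotegerin, averaged 7.75 ± 0.23 and 6.24 ± 0.36 (SD, n = 2 each), a difference of -1.52 (SE 0.24), and was the only member past the test adjusted over the list alone, against 0 over all genes. Bmp4, a bone morphogenetic protein, read 7.54 and 7.84 in the controls and 6.56 and 4.14 in the knockouts, a difference of -2.34 (SE 0.80). Sox9, a transcription factor of cartilage, differed by -1.59 (SE 0.54). Msx2, with a knockout mean below the filter level, differed by -0.81 (SE 0.25), which may be a lower bound in size. The call was lost without control replicate 2 (median -0.25, adjusted p = 0.219 by camera in limma). With all genes tested regardless of level the median was -0.22 and with the stricter filter -1.55, and the call held in both. These medians cover different sets of members. Over refits the adjusted p ran from 0.000655 to 0.219. The macrophage list, with a median of 1.16, and the endothelial list, with -0.53, moved between the same groups.

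**Figure D3:**
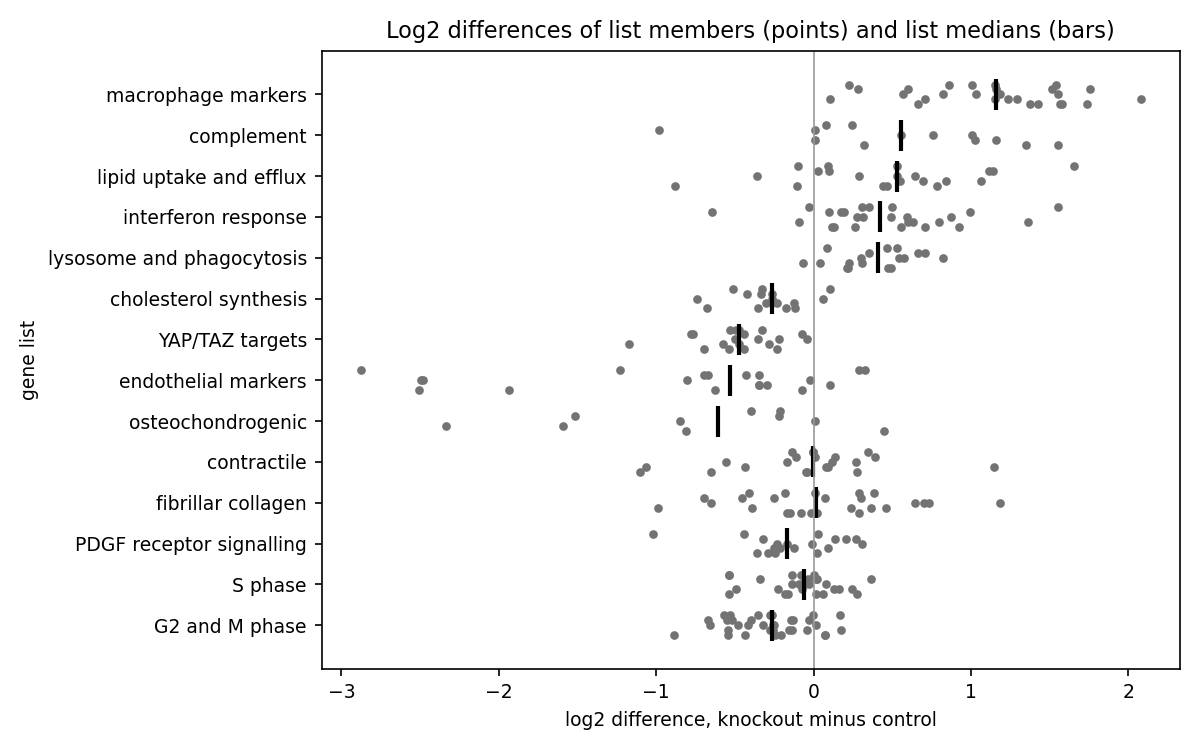
Log2 difference, knockout minus control (x axis), of each tested member (points) of 14 gene lists (y axis), with list medians as bars. The medians ran from -0.61 for the osteochondrogenic list to 1.16 for the macrophage list, and all macrophage members lay above 0.

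Smooth muscle identity genes did not pass as a group. Acta2, smooth muscle alpha actin, averaged 11.2 ± 0.20 and 11.1 ± 0.37 (SD, n = 2 each), a difference of -0.05, and Myh11, smooth muscle myosin heavy chain, differed by 0.09. Leaving out single arrays turned the sign of both. Camera gave the contractile list an adjusted p of 0.977, and 0 members passed adjusted over the list alone. Within it Actg2, the enteric smooth muscle actin, differed by 1.14 (SE 0.36), Ppp1r14a by -1.07 (SE 0.44), Hspb1 by -0.65 (SE 0.21) and Smtn, smoothelin, by -0.55 (SE 0.15). The knockout mean of Ppp1r14a lay below the filter level of 3.02, so its difference may be a lower bound in size. The synthetic list, genes of the dedifferentiated smooth muscle state, had a median of -0.17 with 4 of 15 members higher (adjusted p = 0.564 by camera), and of -0.10 without knockout replicate 2. Its members Col3a1, Myh10, Klf4 and Fn1 differed by 1.18, -0.80, -0.78 and -0.56.

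Extracellular matrix lists went both ways and none was called with all 4 arrays and the planned filter. The list of metalloproteinases and their inhibitors had 11 of 27 members higher and a median of -0.03 (adjusted p = 0.765 by camera), down to -0.077 without control replicate 1. Adjusted over the list alone, Adam8 (1.65) passed as higher and Mmp16 (-1.74, SE 0.20) and Reck (-1.18, SE 0.23) as lower, against 0 over all genes. Mmp16 encodes another membrane-type metalloproteinase and Reck a membrane-anchored inhibitor of such enzymes, and the collagenase gene Mmp13 differed by -1.20 (SE 0.51). The basement membrane list had 8 of 15 members lower and a median of -0.31 (adjusted p = 0.287 by camera), or -0.13 with no filter on dim genes. Of these, 4 passed adjusted over the list alone, against 0 over all genes: the laminin genes Lama2 (-1.20, SE 0.14) and Lamb1 (-0.88, SE 0.18), the perlecan gene Hspg2 (-0.74, SE 0.15) and the nidogen gene Nid1 (-0.61, SE 0.14). The elastic fibre list had a median of -0.25 (9 of 13 lower, adjusted p = 0.238 by camera). Over the members left by the stricter filter on dim genes it was -0.70. Ltbp1, a latent TGF-beta binding protein, passed adjusted over the list alone at -1.65 (SE 0.29). Eln, the elastin gene, read 5.10 and 6.57 in the controls and 3.98 and 4.08 in the knockouts, and Efemp1 and Fbln5 differed by -1.32 and -1.13. Without knockout replicate 1 the elastic fibre list was called lower (median -0.22, adjusted p = 0.0460 by camera, up to 0.523 over refits). Fibrillar collagen and assembly genes had a median of 0.02 and 14 of 26 higher (adjusted p = 0.298 by camera), a sign that flipped to -0.015 with arrays centred on their median. In that list Loxl4 differed by -0.99, Fmod by 0.70 and Col11a1 by -0.65. The collagen list was called higher with the stricter filter (0.07, adjusted p = 0.0474 by camera) and without knockout replicate 2 (0.21, adjusted p = 0.00143 by camera), in a range over refits up to 0.694. Without knockout replicate 1 its median was -0.14. Integrin and adhesion genes had a median of -0.11 with 14 of 23 lower (adjusted p = 0.718 by camera), or -0.044 without control replicate 1 and -0.045 without knockout replicate 2. Itga3 passed adjusted over the list alone at -1.72 (SE 0.23), with Itga2 at -1.38, Ddr2, a collagen receptor, at -1.05 and Itgb8 at 0.81. Between the same groups the macrophage list had a median of 1.16 and the endothelial list of -0.53.

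Growth factor and developmental signalling lists were not called either with all 4 arrays and the planned filter. PDGF receptor signalling genes had a median of -0.17 with 12 of 19 lower (adjusted p = 0.630 by camera). It was -0.089 without control replicate 1 and -0.070 without knockout replicate 1. The receptors Pdgfra and Pdgfrb differed by -0.29 (SE 0.47) and -0.21 (SE 0.40), but 0.41 for Pdgfra without control replicate 2 and 0.31 for Pdgfrb without knockout replicate 2. The ligand Pdgfd differed by -1.02 (SE 0.38), Rasa1 by -0.44, Shc1 by -0.36 and Ptpn11 by -0.32. Early response genes had a median of -0.32 with 14 of 21 lower (adjusted p = 0.168 by camera), among them Egr1 at -0.79 (SE 0.16), Spry4 at -0.81 and Nr4a2 at -0.85, while Atf3 was at 0.88. They were called lower with no filter on dim genes (adjusted p = 0.0427 by camera) and without knockout replicate 2 (median -0.41, adjusted p = 0.0117 by camera), in a range over refits up to 0.737. The median was -0.18 without control replicate 1 and -0.19 without knockout replicate 1. TGF-beta targets had a median of 0.03, which flipped to -0.0022 with arrays centred on their median (9 of 17 higher, adjusted p = 0.298 by camera). Tgfbi, a secreted matrix protein induced by TGF-beta, differed by 2.01 (SE 0.27) and passed adjusted over the list alone, the receptor Tgfbr1 differed by 0.91, Id2 by 0.91 and the ligand Tgfb2 by -0.53. Without knockout replicate 2 the list was called higher (median 0.21, adjusted p = 0.0259 by camera), and without knockout replicate 1 the median was -0.15 (adjusted p = 0.951 by camera, the highest over refits). The Notch list had a median of 0.19 (adjusted p = 0.525 by camera), with Hey2 at -0.43, Hey1 at 0.26 and Notch2 at 0.17. The Wnt list had a median of -0.02 and a mean of -0.04 while camera pointed upward (adjusted p = 0.911), with Rspo3 at -1.14, Sfrp1 at 0.98, Sfrp4 at 0.80 and Sfrp2 at -0.80. For cytokines and chemokines under NF-kappaB the median was 0.10 with 16 of 25 higher (adjusted p = 0.445 by camera). Leaving out control replicates 1 and 2 and knockout replicates 1 and 2 in turn gave 0.045, 0.062, 0.16 and 0.021. Vcam1, an adhesion molecule for leukocytes, passed adjusted over that list alone at -1.20 (SE 0.18), the acute-phase gene Saa3 differed by 2.46 (SE 0.87; 1.15 without control replicate 1 and 3.78 without control replicate 2), Cxcl5 by 1.15 and Cxcl12 by -1.07. The macrophage list moved between the same groups in all of these comparisons.

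Apart from the cholesterol and lipid lists above, metabolic and stress lists were not called with all 4 arrays and the planned filter and scaling. Glycolysis and hypoxia genes had a median of 0.11 with 14 of 21 higher (adjusted p = 0.0629 by camera), with Pdk1 at 1.27 (SE 0.32), Ero1a at -0.59, Pfkl at 0.43 and Pgam1 at 0.32. They were called higher after a second quantile normalisation (adjusted p = 0.0359 by camera), without control replicate 2 (median 0.18, adjusted p = 0.0193 by camera) and without knockout replicate 2 (median 0.14, adjusted p = 0.0259 by camera), in a range over refits up to 0.343. Without control replicate 1 the median was 0.010. Oxidative phosphorylation genes had a median of -0.04 with 21 of 29 lower (adjusted p = 0.709 by camera), or -0.096 without control replicate 1 and -0.026 without control replicate 2, with Ndufa4 at -0.29, Cox5b at -0.27, Ndufv2 at -0.24 and Cox7b at 0.18. NRF2 target genes had a median of -0.25 with 11 of 14 lower (adjusted p = 0.0787 by camera). Nqo1, a quinone reductase, averaged 7.34 ± 0.04 in the controls and 5.46 ± 0.65 in the knockouts (SD, n = 2 each), a difference of -1.89 (SE 0.33), and passed adjusted over the list alone, against 0 over all genes. Me1, Gsta4 and Txnrd1 differed by -0.76, -0.76 and -0.39. The list was called lower with no filter on dim genes (median -0.18, adjusted p = 0.0458 by camera) and without knockout replicate 2 (median -0.40, adjusted p = 0.00176 by camera), while without knockout replicate 1 the median was -0.13 (adjusted p = 0.437 by camera, the highest over refits). Unfolded protein response genes had a median of -0.08 (adjusted p = 0.718 by camera), or -0.028 without control replicate 2, with Chac1 at -0.47, Creld2 at -0.47, Dnajb9 at -0.40 and Sdf2l1 at 0.39. Heat shock genes had a median of -0.16 with 8 of 11 lower (adjusted p = 0.309 by camera), with Hspb8 at -0.48, Hsph1 at -0.36, Hspd1 at -0.21 and Chordc1 at -0.20. Cell cycle inhibitors and p53 targets had a median of -0.16 with 12 of 16 lower (adjusted p = 0.445 by camera), or -0.089 without control replicate 1 and -0.084 without knockout replicate 2, with Sesn1 at 0.53, Eda2r at -0.48, Trp53inp1 at -0.47 and Sesn2 at -0.45.

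Markers of other cell types were uneven, and the macrophage list, with a median of 1.16, moved between the same groups. The pericyte list had a median of 0.32 with 6 of 7 higher (adjusted p = 0.0635 by camera), where Anpep, the aminopeptidase CD13, passed adjusted over the list alone at 1.28 (SE 0.18) and Cspg4 was at -0.96. It was called higher with arrays centred on their median (0.29, adjusted p = 0.0482 by camera) and without control replicate 2 (0.63, adjusted p = 0.00344 by camera), while without control replicate 1 the median was 0.071 (adjusted p = 0.434 by camera, the highest over refits). The adventitial fibroblast list had a median of 0.20 but a mean of -0.14 (adjusted p = 0.718 by camera, pointing upward), or -0.17 without control replicate 1, 0.47 without control replicate 2 and -0.22 without knockout replicate 1, with Cd34 at -2.40 (SE 0.51), Dpt at -1.51, Serpinf1 at 0.52 and Col14a1 at 0.38. The mesothelial and epithelial list had a median of -0.66 over 5 genes (adjusted p = 0.326 by camera), or 0.036 without control replicate 2 and -0.041 with no filter, where the keratin gene Krt19 passed adjusted over the list alone at -1.23 (SE 0.14). Skeletal and cardiac muscle genes had a median of -0.03 over 6 genes (adjusted p = 0.709 by camera), with Acta1 at -1.67 (SE 0.75) and Tnnt2 at -1.09. Adipocyte genes had a median of 0.45 over 4 genes (adjusted p = 0.156 by camera). They were called higher with the title number as a block (adjusted p = 0.0168 by camera) and without control replicate 2 (median 0.76, adjusted p = 0.00697 by camera), while without control replicate 1 the median was 0.11 (adjusted p = 0.777 by camera, the highest over refits) and without knockout replicate 2 it was 0.18. Schwann and neural genes had a median of 0.17 over 8 genes (adjusted p = 0.309 by camera), or 0.37 without control replicate 1 and 0.012 with no filter, with Gap43 at -0.18 and Mbp at 0.17. Lymphocyte and erythroid lists were not tested, because each had fewer than 3 members left to test. Of 15 lymphocyte genes, 10 were named on the array and 1 reached the filter level. Of 9 erythroid genes, only 1 was named on the array, and it lay below that level.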

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

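All alternatives here were planned except the lists without shared members, which were chosen after the data were seen. The number of genes called stayed at 0 in each alternative fit and at an adjusted p under 0.1. It was 1465 at an unadjusted p under 0.05, and 343 with an absolute log2 difference of at least 1 as well. Mmp14 kept its direction in each fit, from -0.82 to -0.48 (limma, adjusted p from 0.256 to 0.524). Of 2240 values of the other 175 named genes under alternatives, 2224 kept direction and side of the threshold and 16 changed sign. Most of these genes were named because their groups did not overlap, so leaving out an array could not change their sign. No value passed the threshold in any fit, so the count does not measure how stable the genes are. Leaving out 1 array moved the difference by over 1.5 times for 82 of these 175 genes, and the median for 28 of the 31 lists that were not called. The number of genes at an unadjusted p under 0.05 was 929 with the stricter filter, where fewer genes were tested, and 975 to 1535 over leave-one-out fits, lowest without control replicate 1. With the title number as a replicate block the count was 1527, 0 genes were called and 11 lists passed, the G2 and M phase and adipocyte lists among them. Whether the numbers pair the arrays stays open. The correlation of same-numbered deviations over all tested genes was 0.045, but the cell cycle lists described below followed the title number. Of the gene lists called, 9 in the fit as reported, there were 0 with camera at an estimated correlation, 0 with fry directional (smallest adjusted p = 0.234), 14 with fry mixed (smallest adjusted p = 0.000918), 8 without shared members, and 10 to 16 over leave-one-out fits, highest without knockout replicate 2. The median log2 difference of all tested genes was -0.05 as deposited, -0.04 after a second quantile normalisation and -0.08 with arrays centred on their median. Values that changed sign follow, and the cause was not tested. Cox7b was -0.054 with the mean of all rows. With no filter the medians of the Notch, skeletal and cardiac muscle and sex-linked lists were -0.080, 0.051 and 0.022. With the stricter filter those of the Wnt and Schwann and neural lists were 0.035 and -0.032. Quantile normalisation gave the sex-linked list 0.011, and centring gave the collagen list -0.015 and the TGF-beta list -0.0022. Leaving out each array in turn gave ranges of -0.36 to 0.34 for Tagln, -0.066 to 0.21 for Arhgdib, -0.52 to 0.083 for Ccn1, -0.26 to 0.11 for Ccn2, -0.31 to 0.21 for Acta2, -0.14 to 0.33 for Myh11, -0.99 to 0.41 for Pdgfra, -0.92 to 0.43 for S1pr1 and -0.74 to 0.31 for Pdgfrb. List medians ranged likewise from -0.26 to 0.10 for contractile genes, -0.31 to 0.22 for S phase, -0.88 to 0.30 for G2 and M phase, -0.14 to 0.21 for collagen, -0.15 to 0.21 for TGF-beta, -0.023 to 0.19 for Notch, -0.084 to 0.032 for Wnt, -0.22 to 0.47 for fibroblast, -0.16 to 0.036 for skeletal and cardiac muscle, -0.73 to 0.036 for mesothelial, -0.13 to 0.016 for ribosomal protein, -0.28 to 0.20 for histone and -0.12 to 0.025 for sex-linked genes. Genes with a mean log2 value below the filter level of about 3.02 were outside the tests.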

Other observations

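Cell cycle lists followed the title number of the arrays more than the genotype. The G2 and M phase list, 35 genes of mitosis, had a mean deviation of -0.23 in control replicate 1, 0.52 in control replicate 2, -0.77 in knockout replicate 1 and 0.48 in knockout replicate 2. Its median difference between groups was -0.26 with 30 of 35 members lower, the groups overlapped for every member, and camera in limma gave an adjusted p of 0.309. Without knockout replicate 1 the median was 0.30 (adjusted p = 0.00183 by camera), and without knockout replicate 2 it was -0.88 (adjusted p = 1.35e-13 by camera). Without control replicate 1 it was -0.68 (adjusted p = 0.000699 by camera), and without control replicate 2 it was 0.09. With the title number as a block the list was called lower (adjusted p = 0.0023 by camera), and over all refits its adjusted p ran from 1.35e-13 to 0.713. The S phase list had a median of -0.06 (17 of 28 lower, adjusted p = 0.950 by camera), with Mcm4 at -0.54, Tipin at -0.54, Pcna at 0.37 and Ung at -0.14. Its deviations were -0.16, 0.25, -0.32 and 0.24 in the same order of arrays, and its median was 0.22 without knockout replicate 1 (adjusted p = 0.0368 by camera) and -0.31 without knockout replicate 2 (adjusted p = 0.00269 by camera), in a range over refits up to 0.986. Histone transcripts had a median of 0.04 and a mean of -0.06 over 7 genes while camera pointed upward (adjusted p = 0.911), with deviations of -0.20, 0.26, -0.33 and 0.27.

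Ribosomal protein genes had a median of -0.06 with 21 of 30 lower (adjusted p = 0.718 by camera). Rps16, below the filter level in the knockouts, was at -0.47, Rpl11 at -0.35, Rpl5 at 0.24 and Rps3 at -0.12. Without control replicate 1 the median was -0.13 and the list was called (adjusted p = 0.0361 by camera, up to 0.881 over refits), and without control replicate 2 the median was 0.016. Small RNA host and long non-coding genes had a median of -0.19 (9 of 11 lower, adjusted p = 0.445 by camera), or -0.11 without control replicate 2, with Neat1 at 0.54, Meg3 at -0.46, Zfas1 at -0.39 and Snhg12 at -0.35. Y-linked genes were present in all 4 arrays, with Eif2s3y at 6.61 to 6.78, while the X-inactivation transcript Xist read 2.11 to 2.51. The sex-linked list had a median of -0.03 and a mean of -0.02 over 3 genes while camera pointed upward (adjusted p = 0.965), and Kdm5d differed by 0.07.

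In the weighing that follows, the test of the smooth muscle share, that of dilution, that of the brighter genes of the second endothelial list and that of other splits of the arrays were chosen after the results they measure were seen. The macrophage list was higher in the knockout arrays, with a median of 1.16. A loss of smooth muscle cells with all other cells unchanged would raise every other cell type alike. The endothelial median was -0.53 (bootstrap interval over members -1.02 to -0.32), in the opposite direction. This median was known when the test was chosen. Endothelial cells may also have fallen for a reason of their own, so it does not decide against such a loss. Contractile genes, which such a loss would lower, had a median of -0.01, or -0.26 to 0.10 with 1 array left out. A share lowered by added macrophages would not raise endothelial genes, so this test cannot decide on it. More leukocytes in the knockout cultures may be the source. A second list of 33 pan-leukocyte genes, none on the macrophage list, had a median of 1.18 with 33 of 33 members higher, where 10000 matched random lists reached at most 0.18. Its members with the highest control means, Cyba, Arhgdib and Lcp1, differed by 0.76, 0.07 and 1.16, and Lyz2, at 11.0 in the controls, by 0.22, while macrophage-like gene expression within smooth muscle cells and the genotype itself stay open and untested.

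The endothelial list was lower in the knockout arrays, with a median of -0.53, after an isolation that removed the adventitia but names no sort against endothelial cells. On that list 17 members were lower, but Kdr (0.32), Vwf (0.29) and Flt1 (0.10) were higher. Fewer endothelial cells in the knockout cultures is a candidate explanation that the data leave open. A second list of 22 endothelial genes, none on the first, met the bound set in advance against it: its median was 0.069 (bootstrap interval over members -0.30 to 0.39), within the 95% range of -0.15 to 0.09 of matched random lists. That bound was too simple, because 14 of the 22 had a control mean under 4 and little room to fall, members moved both ways without overlap between groups, 9 higher and 8 lower, and the 8 with a control mean of at least 4 had a median of -0.051 with an interval of -1.18 to 0.80 that holds both 0 and the first list's median. Among these 8, Cd93 (0.80), Fli1 (0.80), Stab1 (0.61) and Ecscr (0.14) were higher and Palmd (-2.43), Adgrl4 (-1.18), Tm4sf1 (-0.57) and S1pr1 (-0.24) lower; Cd93, Fli1 and Stab1 are also expressed in myeloid cells, whose list was higher by 1.16, and an effect of the genotype was not tested.

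The YAP/TAZ target list was lower in the knockout arrays, with a median of -0.48. Dilution of smooth muscle RNA by other cells would lower contractile and collagen genes by as much, but the contractile median lay 0.47 above the YAP/TAZ median (bootstrap interval over members 0.29 to 0.60) and the collagen median 0.49 above it (0.27 to 0.78). The mean deviation of the YAP/TAZ list minus that of the contractile list was 0.21 and 0.19 in the control arrays and -0.29 and -0.12 in the knockout arrays. These values argue against dilution as the whole cause, provided that contractile and collagen genes did not move for another reason. With 1 array left out, the contractile median ran from -0.26 to 0.10 and the collagen median from -0.14 to 0.21. Loss of MT1-MMP, a difference in culture density between preparations, or a change in the kinds of cells present may each lie behind the remaining difference of 0.47, and none of these was tested.

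The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05, and 1 of the 3 splits, the real one, gave as many as 1465 genes at an unadjusted p under 0.05 (limma), where the highest other split gave 384.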
